A study of Gallus gallus with 2400 samples.

How the data were processed

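The series holds 2 tables that the authors deposited for 2400 capture sites of 6 groups. Per the labels, dissociated papilla cells were loaded on microfluidic chips, 400 cells were taken per group, and 3' end libraries were sequenced with paired-end reads on a HiSeq2500. Per the submitters' processing notes, reads were aligned with STAR 2.7.0a to the chicken assembly GRCg6a, assigned to genes with Subread 1.6.3 and analysed further with Seurat, whose version is not given. The raw table has the unit count: the deposited values are whole numbers of assigned reads, with no molecule tags per the labels. The normalized table has the unit score: the authors' values are whole numbers from 0 to 35, and how they were scaled is not given in the sources used here. No cell's normalized values follow the order of its raw counts throughout, and their total per cell runs from 1167 to 6455.

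Both tables list 23842 genes, and the rows were taken to be in the same order. The raw table names genes by numeric identifier and the normalized table by symbol. Over the kept cells 100% of entries are above 0 in both tables or 0 in both, 18014 of 19168 detected genes have a unique detection pattern, and all 8162 symbols made of LOC and a number match the identifier in the same position. Of the identifiers 19594 occur in the reference gene table, 18317 of them with the deposited symbol. That reference is of a later assembly, so no position was used. No 2 capture sites have identical counts.

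Groups were taken from the labels: 10 capture codes of 40 sites for each group. A capture code is a part of the chip and not an animal or culture, so it was used for ranges only. Since each group is 1 sample, no test was made, and no p-value or number of changed genes was computed. Kept cells are the 1054 cells of the normalized table, which is the authors' own filter: 261 intact, 236 day 0, 94 day 2 control, 112 day 2 streptomycin, 169 day 6 control and 182 day 6 streptomycin cells. They have 1005 to 3984 detected genes, 20996 to 826531 reads and at most 12.4% mitochondrial reads. Of the sites left out, 92 have more genes than any kept cell.

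Raw counts were summed over the kept cells of a group and divided by the total, in CPM. A ratio is log2 of (CPM + 1) over (CPM + 1). Sums carry exact Poisson intervals, ratios of sums the exact conditional binomial interval, and shares exact Clopper-Pearson intervals, all at 95%. A fold against a group without a read is a lower bound from 3 counts over the group, written "at least", and a share of 0 is bounded by 3 cells in the group. With 1 to 3 reads in the lower group the ratio and its interval are printed. Folds are of CPM without the added 1.

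Cells were clustered in scanpy 1.11.5 (anndata 0.12.19, igraph 0.11.9) from log-normalised counts of all kept cells: 2000 variable genes, 15 principal components, 15 neighbours and Leiden clusters at resolution 1.0. A cluster was named X-like when at least 3 fixed markers of X had a log2 difference of 1.0 over the other cells and a read in 20% of its cells, with a mean difference of at least 0.5 over all markers of X. Among the 10 leading genes of the cluster no other type was allowed more markers than X. Clusters that met this for no type are called unnamed, and clusters are numbered by size. For shares of cells with a read, each cell was thinned to 20000 reads, which no kept cell falls under. Doublets were scored with Scrublet within each group at an expected 5%. Its automatic threshold called 6, 5, 63, 4, 5 and 1 cells from intact to day 6 streptomycin, so it failed in the day 2 control, where the call is 67.0% of cells. No called cell was removed from the main values.

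The 29 gene lists, 9 of cell type markers and 20 of pathways or functions, were fixed by name before the data were examined, as were the groups, the 8 comparisons, the cell filter, the rule for naming genes and the first set of alternatives. A list median takes members with at least 5 CPM in the higher group. Its percentile is among 10000 random lists of the same size drawn from 20 bins of mean expression. Genes were named by rule. The rule takes the 12 genes with the highest and the 12 with the lowest log2 ratio in each streptomycin comparison, and 8 each way in the others. A gene needs a symbol, 50 CPM and a read in 10% of the cells of the higher group, and the same direction with equal weight per cell and without each capture code. From each list the rule takes up to 4 members of at least 20 CPM with the largest ratios, and MYO7A, ATOH1, SOX2, TECTA and TECTB are printed always. The text prints part of the genes so named, leaning to those of known function. The lists whose medians count as main results were picked after the medians were seen and before the alternatives were computed.

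Alternatives fixed beforehand were a threshold filter (1000 genes, 20% mitochondrial reads, 1285 cells), a loose filter (200 genes, 2370 cells), resolutions of 0.5 and 2.0, 30 components, 4 hair cell markers after thinning in place of clusters, and leaving out called doublets. For ratios they were the mean of per-cell CPM, edgeR 4.0.16 TMM scaling in R 4.3.3, pseudocounts of 0.1 and 5 CPM, no minimum CPM, totals without mitochondrial and ribosomal genes, the authors' normalized values, each capture code left out, and supporting cell-like cells without a read of MYO7A, OTOF or CALB2. Chosen after seeing the data were leaving out the 5% of cells with the highest doublet scores, the threshold filter without the capture code that has no kept cell, supporting cell-like cells without cluster 10, and 4 comparisons within clusters or classes. Code ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

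The steps were tested on simulated data: counts of both groups were drawn from a Poisson distribution around their pooled expression, with 50 genes at each known fold. For the day 2 comparison, over 6944 genes, folds of 4, 2, 0.5 and 0.25 came back as median log2 ratios of 1.98, 0.97, -0.98 and -1.94, with 98, 96, 92 and 92% of intervals holding the true fold. For the day 6 comparison, over 7123 genes, they came back as 1.96, 0.97, -1.01 and -1.96, with 92, 100, 98 and 92%. Of unchanged genes 95.3% and 95.0% of intervals held the true fold. For all genes the true fold is taken after the shift that the changed genes give to the totals of the groups. The simulation holds counting error only and no difference between cultures.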

Results

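The basilar papilla is the hearing epithelium of birds. It holds mechanosensory hair cells and the supporting cells around them, and unlike the mammalian organ of Corti it replaces lost hair cells. Here single cells of chick papillae were sequenced at 6 points of an explant culture: directly after dissection (intact), after 24 h in control medium (day 0), after 48 h more with or without 78 uM streptomycin (day 2), and at day 6. By day 6 the streptomycin explants had spent 96 h back in drug-free medium, and the day 6 controls had been in control medium for 144 h after day 0. Streptomycin is an aminoglycoside antibiotic that kills hair cells. Each group holds 400 capture sites, read at the 3' end of transcripts. The depositors kept cells from 65.25% (intact), 59% (day 0), 23.5 and 28% (day 2 control and streptomycin), 42.25 and 45.5% (day 6 control and streptomycin) of these sites. These cells carry 152314847 assigned reads. Median reads per cell were 84433, 84002, 193293, 120960, 188672 and 183522 in the same order, and median detected genes were 3027, 3134.5, 2749, 2635, 1871 and 1940.

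No animal, pool or culture is named for any cell, so each group counts as 1 sample, no test was possible and there is no replicate check. Values are sums over cells in CPM (reads of a gene scaled by all reads of the group), given for both groups. Intervals are exact 95% intervals that cover counting error only. The counts are reads without molecule tags, so even this error is understated. List medians are log2 ratios over the measured members of gene lists fixed by name. The percentile of a list among 10000 random lists of like expression is given as a description of these libraries.

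Cells were grouped into 14 clusters and named by their markers to ask which cell types each culture point holds. Hair cell-like cells were the largest class before and after preincubation, at 67.8% (61.8 to 73.4) of intact and 76.7% (70.8 to 81.9) of day 0 cells. With streptomycin their share was lower than in the control at both days: 17.0% (10.5 to 25.2) against 43.6% (33.4 to 54.2) at day 2, and 20.3% (14.7 to 26.9) against 40.8% (33.3 to 48.6) at day 6. Other settings move these shares. At day 2 they are 3.57 against 41.5% at double the clustering resolution, 7.25 against 38.9% with fixed thresholds, 9.16 against 13.6% over all sites of 200 genes or more and 37.5 against 55.3% by 4 markers. Without called doublets they are 14.8 against 74.2%. At day 6 they are 10 against 17.8% over all such sites. The largest part of the class is in cluster 1 in the day 2 control, in cluster 5 in the day 6 control and in cluster 6 with streptomycin at both days. Cluster 6 is led by ATOH1, a transcription factor of early hair cell differentiation. It holds no intact cell (at most 1.15%) and no day 0 cell (at most 1.27%). It holds 2 and 15 day 2 cells and 22 and 35 day 6 cells (control and streptomycin). That is 2.13% (0.259 to 7.48) against 13.4% (7.69 to 21.1) of cells at day 2 and 13.02% (8.34 to 19.04) against 19.2% (13.8 to 25.7) at day 6. The other hair cell-like clusters make up 41.5% (31.4 to 52.1) of day 2 control cells against 3.57% (0.982 to 8.89) with streptomycin, and 27.8% (21.2 to 35.2) against 1.10% (0.133 to 3.91) at day 6. The day 2 share of the ATOH1-led cluster depends on the setting. With fixed thresholds that cluster holds 0 control and 2 streptomycin cells at day 2, and 21 and 37 at day 6. An unnamed cluster with ATOH1 and PENK among its leading genes then holds 5 and 34 at day 2, and 4 and 4 at day 6.

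Supporting cell-like shares of all cells lay close together, at 25.5% (17.1 to 35.6) in the control and 28.6% (20.4 to 37.9) with streptomycin at day 2, and 34.3% (27.2 to 42) and 29.7% (23.1 to 36.9) at day 6. They were 31.8% (26.2 to 37.8) of intact and 14.8% (10.6 to 20.02) of day 0 cells. Among cells that are not hair cell-like they were 45.3% (31.6 to 59.6) against 34.4% (24.9 to 44.98) with streptomycin at day 2, and 58% (47.7 to 67.8) against 37.2% (29.4 to 45.7) at day 6. Cluster 3 holds the largest part of this class at day 0, at day 2 and in the day 6 control, and cluster 8 in the day 6 streptomycin group. In intact tissue it is cluster 4, with 76 of its 80 cells there, and a cluster held mostly by 1 library may be that library. Mesenchyme-like cells were 0, 2.12, 17.0, 28.6, 12.4 and 20.3% of cells from intact to day 6 streptomycin. Glia-like cells were 0, 0, 4.26, 2.68, 3.55 and 14.3%, and leukocyte-like cells 0, 0.424, 0, 3.57, 1.18 and 5.49%. A share of 0 is at most 1.15% in intact tissue, 1.27% at day 0 and 3.19% in the day 2 control. Unnamed clusters hold 0.383, 5.93, 9.57, 19.6, 7.69 and 9.89%. Cells with a read of MYO7A, a myosin of the hair bundle, were 13.4% with streptomycin against 50.0% in the day 2 control (8.93 against 43.6% with each cell thinned to 20000 reads), and 30.8 against 49.7% at day 6 (21.98 against 39.6% thinned). Among mesenchyme-like and leukocyte-like cells, of median depth 140236 reads, the background share of MYO7A was 10.2% (2.34% thinned). ATOH1 was read in 37.5 against 15.96% of day 2 cells (30.4 against 14.9% thinned) and in 45.1 against 37.3% of day 6 cells (31.3 against 26.6%), over a background of 17.97% (7.81% thinned).

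**Figure D1:**
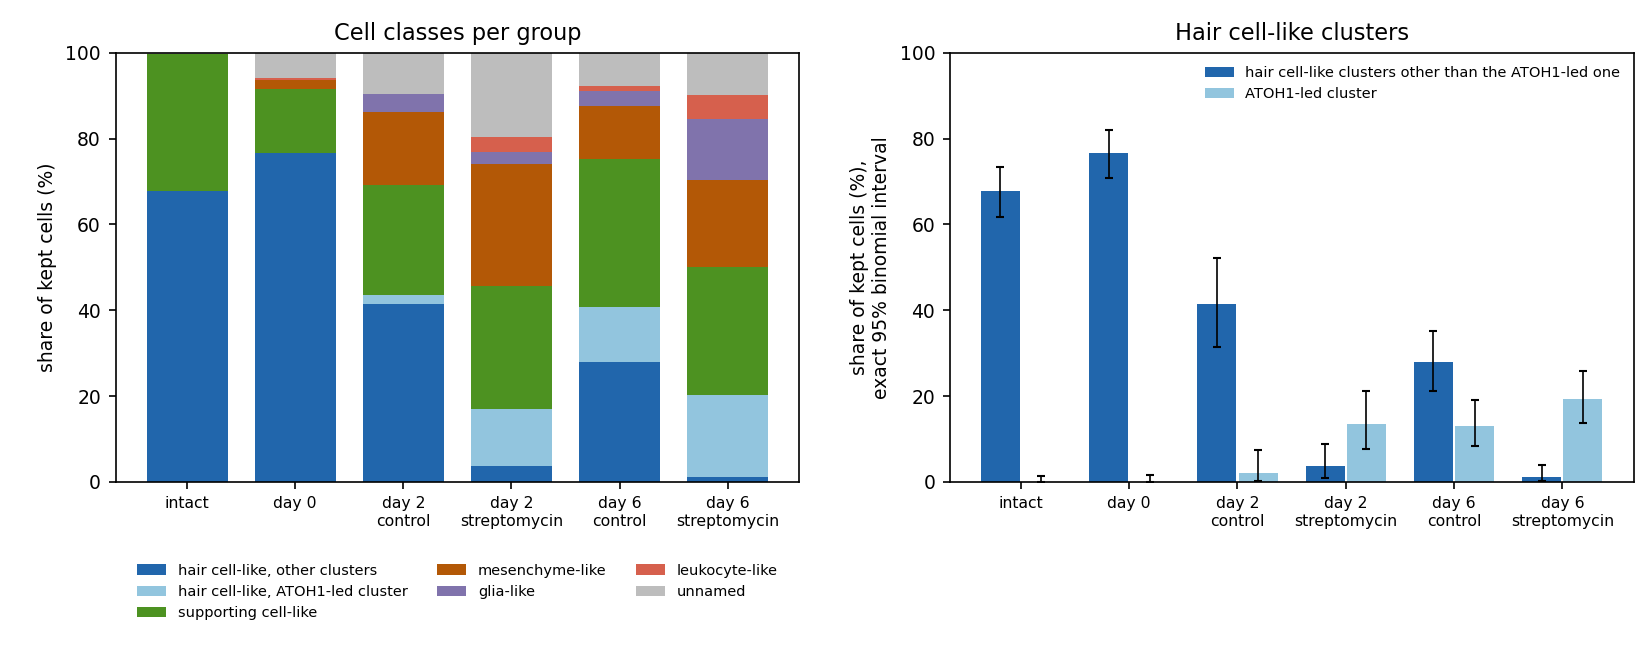
Left, share of kept cells (%) in each cell class per group, with hair cell-like cells split into the ATOH1-led cluster and the others; right, these 2 shares as bars with exact 95% binomial intervals. The other hair cell-like clusters hold 3.57% of day 2 streptomycin cells against 41.5% of control cells, and the ATOH1-led cluster 13.4 against 2.13%.

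What differs between streptomycin-treated and control explants at day 2? Genes of hair cells, of their bundle and of their synapse were lower with the drug almost without exception. Interferon response, inflammatory, cell cycle and Notch pathway genes were higher, as were tectorial membrane and inner ear matrix genes and leukocyte markers. ATOH1 itself was higher, 396.5 against 65.9 CPM (gene ID 101750213, 6.02-fold higher, 5.66 to 6.4).

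Of 27 measured hair cell genes 25 were lower (median -2.37, percentile 0), among them the calcium buffer gene OCM (gene ID 386586, 241.4 against 5204 CPM, 21.6-fold lower, 20.9 to 22.3). The acetylcholine receptor gene CHRNA9 (gene ID 395522, 0.196 against 28 CPM), TMIE (gene ID 769596, 0 against 26.5) and CABP2 (gene ID 429967, 6.61 against 95.6) were lower with it. So was MYO7A (gene ID 419085, 96.1 against 464.3 CPM, 4.83-fold lower, 4.57 to 5.11). All 23 measured genes of the hair bundle and mechanotransduction were lower, at a median of -2.40, with GRXCR2 (gene ID 771645, 1.18 against 80.8 CPM, 68.5-fold lower, 43.2 to 115.96) and FSCN2 (gene ID 429198, 22 against 242.9 CPM). The same holds for 11 of 12 ribbon synapse genes (median -2.58), including the glutamate transporter gene SLC17A8 (gene ID 427877, 24.9 against 262.3 CPM) and the potassium channel gene KCNMA1 (gene ID 374065, 19.3 against 190.3 CPM). The potassium channel gene KCNG4 (gene ID 395901, 0 against 74.5 CPM, at least 379.1-fold lower) had no read in the treated cells. In the nascent hair cell list 10 of 13 were lower (median -1.85) and HES6 (gene ID 424829, 26.1 against 1.18 CPM) was among the 3 higher. Neuron markers were also lower in 4 of 6. No cluster was named neuron-like, and the neuron marker NEFM is among the leading genes of hair cell-like cluster 1. All 3 measured erythrocyte genes were lower too (median -4.80), but the median is 0 without capture code SC503 of the control, so this list rests on red cell RNA in 1 code. Cholesterol synthesis genes were lower in 12 of 14 (median -0.90, percentile 0.12), as in SQLE (gene ID 420335, 18.9 against 66.2 CPM) and HMGCS1 (gene ID 396379, 154.6 against 459.1).

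Interferon response genes were higher in 14 of 16, at a median of 2.04 and percentile 100. The largest ratio of the comparison belongs to IFI6 (gene ID 403120, 370.8 against 0.642 CPM, 577-fold higher, 330.1 to 1118). Its size depends on a low control: intact tissue, day 0 and the day 6 control all hold more IFI6 than the day 2 control, as given below. Within the list ZNFX1 (gene ID 419218, 29.7 against 0.749 CPM) and PARP14 (gene ID 101747378, 40.4 against 2.62) and the RNA sensor gene IFIH1 (gene ID 424185, 28.7 against 3.96 CPM) come next. 10 of 13 JAK-STAT and inflammatory genes were higher (median 1.25), led by the chemokine genes IL8L2 (gene ID 396495, 77.3 against 2.19 CPM) and IL8L1 (gene ID 395872, 113.8 against 7.71). All 10 leukocyte markers were higher (median 3.99, or 4.22 with zero genes at their bound), such as CTSS (gene ID 425657, 121.3 against 3.05 CPM, 39.8-fold higher, 30.6 to 52.7), beside a leukocyte-like share of 3.57% against 0 (at most 3.19%). Cell cycle genes were higher in 13 of 16 (median 1.94, percentile 100), with TOP2A (gene ID 395570, 44.3 against 3.64 CPM), CENPF (gene ID 395357, 114.2 against 14.3) and BIRC5 (gene ID 374078, 60.5 against 8.35) and the replication gene MCM2 (gene ID 416027, 33.1 against 4.34 CPM). 8 of 13 Notch pathway genes were higher (median 1.06): HES5 (gene ID 419392, 83.3 against 1.07 CPM, 77.8-fold higher, 50.2 to 127.8), HES4 (gene ID 395128, 99.4 against 10.2 CPM) and LFNG (gene ID 395790, 114.4 against 30.7) and the ligand gene DLL1 (gene ID 395820, 67.5 against 19.7 CPM). Supporting cell genes were higher in 13 of 17 (median 0.61), SOX2 (gene ID 396105, 8.71 against 0.803 CPM) among them. Inner ear matrix genes were higher in 10 of 11 (median 0.91), as in OC90 (gene ID 420326, 188.4 against 33.1 CPM) and COCH (gene ID 395779, 1445 against 475.2). COCH is a leading gene of mesenchyme-like cluster 7 and OC90 of unnamed cluster 9. These clusters hold 23.2 against 13.8% and 8.93 against 3.19% of day 2 cells (streptomycin against control). TECTB (gene ID 396320, 1411 against 726 CPM) and TECTA (gene ID 395686, 42.96 against 25.5) were both higher. YAP and matrix genes such as CTGF (gene ID 374135, 88.3 against 16.2 CPM) and CYR61 (gene ID 429089, 183.7 against 43.5) were higher in 10 of 15. So were apoptosis genes in 8 of 12 with CASP8 (gene ID 395284, 46.4 against 8.78 CPM), and all 10 immediate early genes (median 0.68). Outside the lists the sodium channel gene SCNN1A (gene ID 396050, 97.2 against 0.749 CPM, 129.7-fold higher, 77.03 to 237.8) and CSTA (gene ID 418268, 397.7 against 18.6 CPM, 21.4-fold higher, 19.2 to 23.9) stood high. Leaving out 1 capture code moves some medians further, at most to 1.18 for the cell cycle list (code SC512), 0.51 for the inflammatory list (code SC507), 0.46 for the Notch list (code SC507), 3.36 for the leukocyte list (code SC507), -2.99 for the bundle list (code SC508) and -3.46 for the ribbon synapse list (code SC508). These all-cell sums mix cell types whose shares differ between the arms, so a ratio here is of the tissue and not of a cell.

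**Figure D2:**
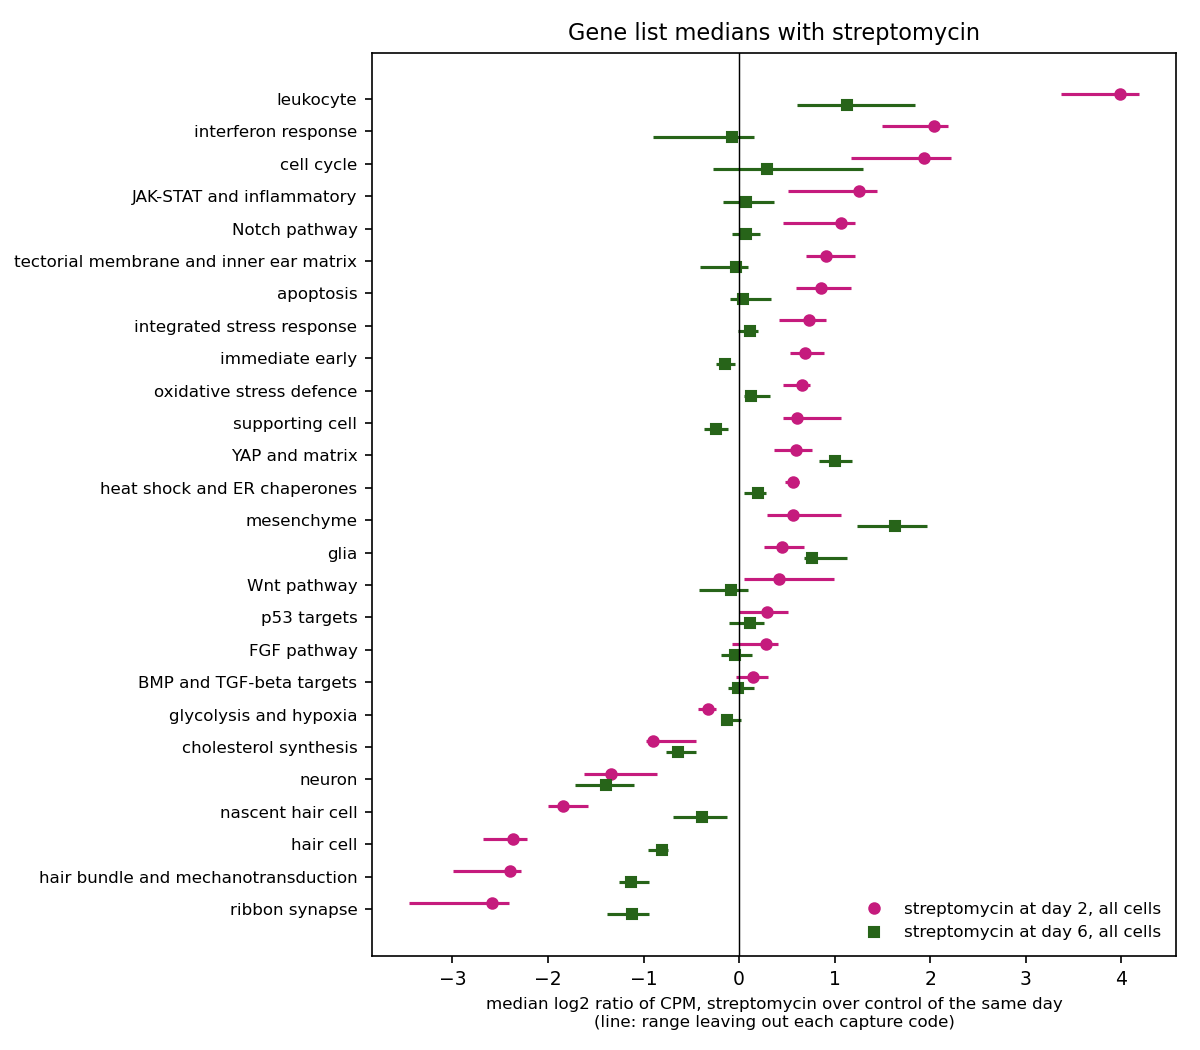
Median log2 ratio of CPM, streptomycin over control of the same day, for each gene list with 5 or more measured members on both days (circles day 2, squares day 6); lines span the values when each capture code is left out. The hair cell list lies at -2.37 at day 2 and -0.81 at day 6, and the interferon response list at 2.04 and -0.08.

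Within supporting cell-like cells alone, does the same response to streptomycin appear at day 2? The interferon response genes were again higher, in 32 treated cells against 24 control cells with 3890491 and 3522723 reads. Cell cycle genes were higher too, but less firmly: their median was 0 without the supporting cell-like cluster of the weakest markers. Supporting cell and Notch pathway genes were mixed, and cholesterol synthesis genes were lower.

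13 of 15 interferon response genes were higher, at a median of 2.11 (percentile 99.6). IFI6 (816 against 0.284 CPM) has 1 read in the control cells, a ratio of 2874 with an interval of 515.5 to 113550. IFIH1 (55.8 against 0 CPM), MX1 (gene ID 395313, 38.3 against 0) and USP18 (gene ID 418167, 33.7 against 0) have none. LY6E (gene ID 395550, 95.6 against 0 CPM, at least 112.3-fold higher), also an interferon-induced gene, and GIF (gene ID 770547, 378.4 against 0 CPM, at least 444.3-fold higher) were unread in the control. Leukocyte markers read in these cells were higher in 3 of 4 (median 2.19, percentile 93.4). Cell cycle genes were higher in 11 of 12 (median 2.95, or 2.98 with zero genes at their bound, percentile 94.7), with MCM2 (24.2 against 0 CPM), TOP2A (30.3 against 0.284) and MCM6 (gene ID 424295, 59.4 against 8.23). Leaving out each capture code in turn gives list medians from 1.49 without capture code SC513 to 3.33 without code SC507. Without cluster 10, the supporting cell-like cluster of the weakest markers, the cell cycle median is 0 and the TOP2A ratio -0.43 in place of 4.61. JAK-STAT and inflammatory genes were higher in 8 of 12 (median 1.47), IL8L1 (278.1 against 0 CPM) and NFKBIZ (gene ID 418404, 89.4 against 9.94) among them. JAK2 (gene ID 374199, 2.57 against 47.1 CPM) was lower, but higher without called doublets (ratio 1.90 in place of -3.75). HES5 (156.5 against 5.68 CPM) and HES4 (38.04 against 2.84 CPM) were higher as in the whole tissue, and so was SOX2 (28.3 against 0 CPM, at least 33.2-fold higher). HEY2 (gene ID 421718, 38.8 against 156.4 CPM) and the glutamate transporter gene SLC1A3 (gene ID 395443, 201.5 against 497.6 CPM) were lower. The supporting cell list stands at 11 higher of 17 (median 0.11) and the Notch pathway list at 7 of 13 (median 0.19). The tectorial membrane and inner ear matrix list, higher in the whole tissue, stands here at 6 of 10 (median 0.12, percentile 61.6). Cholesterol synthesis genes were lower in 10 of 12 (median -0.62, 0.11 without called doublets), as in INSIG1 (gene ID 420442, 43.7 against 214.6 CPM) and HMGCS1 (329.8 against 857). FGF pathway genes were lower in 9 of 11. CACNA1B (gene ID 374169, 0 against 193.3 CPM, at least 250.7-fold lower), a calcium channel gene, and the collagen gene COL22A1 (gene ID 420315, 0 against 160.4 CPM) were not read with streptomycin. ATOH1 (347.8 against 148.2 CPM, 2.35-fold higher, 2.12 to 2.6) was read in 46.9 against 37.5% of these cells. With cells chosen by fixed thresholds instead, its log2 ratio is -1.17 in place of 1.23 and that of MCM2 -0.84 in place of 4.65. TECTB (4420.5 against 3619 CPM) and TECTA (158.6 against 133.7) were close (TECTB has the opposite sign, -0.29, by the fixed thresholds), and MYO7A (0.257 against 1.14 CPM) rests on 1 and 4 reads. MCM2, SOX2, CACNA1B and COL22A1 were read in 3 cells of the higher group, and TOP2A, IL8L1, MX1 and JAK2 in 2. Without 1 capture code other medians move at most to 3.38 for the interferon list (code SC506), 0.65 for the inflammatory list (code SC512), 0.76 for the Notch list (code SC504) and 0.26 for the supporting cell list (code SC502).

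At day 6, 4 days after the drug was withdrawn, which differences from the control remain? Hair cell genes were still lower, by less than at day 2. Mesenchyme, matrix and leukocyte genes were higher, cholesterol synthesis genes were lower, and the interferon response list no longer stood apart.

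21 of 27 hair cell genes were lower with streptomycin (median -0.81, percentile 0), among them TMIE (0.0245 against 20.5 CPM), CHRNA9 (0 against 33.2 CPM, at least 451.9-fold lower), CABP2 (14.8 against 159.5 CPM) and the actin bundler ESPN (gene ID 395461, 40.1 against 212.9 CPM). MYO7A (174.7 against 412.9 CPM, 2.36-fold lower, 2.3 to 2.43) was lower as well, whereas ATOH1 (427.1 against 249.3 CPM, 1.71-fold higher, 1.67 to 1.76) was higher. Bundle genes were lower in 21 of 24 (median -1.13). All 12 ribbon synapse genes were lower (median -1.12), including KCNMA1 (20.02 against 133.1 CPM) and the calcium channel gene CACNA1D (gene ID 395895, 45.7 against 205.5 CPM). The lowest ratios of the comparison include FAM13AL (gene ID 100857497, 1.15 against 134.9 CPM, 117.1-fold lower, 87.9 to 159.6), S100Z (gene ID 431598, 28.2 against 605 CPM, 21.5-fold lower, 20.2 to 22.8) and the neurofilament gene NEFM (gene ID 396206, 4.75 against 111.3 CPM, 23.4-fold lower, 20.3 to 27.2). Of the neuron markers 5 of 6 were lower (median -1.39), with no cluster named neuron-like and NEFM also a leading gene of hair cell-like cluster 1. All 12 mesenchyme genes were higher (median 1.64, percentile 100), COL6A1 (gene ID 396000, 552 against 134.9 CPM), COL1A2 (gene ID 396243, 1904 against 552) and LUM (gene ID 417891, 235.1 against 72.97) among them, beside mesenchyme-like shares of 20.3 against 12.4% of all cells and 25.5 against 21% of those not hair cell-like. 12 of 14 YAP and matrix genes were higher (median 1.01), led by the smooth muscle actin gene ACTA2 (gene ID 423787, 777 against 51.3 CPM, 15.2-fold higher, 14.5 to 15.9), FN1 (gene ID 396133, 1043 against 247.3 CPM) and COL4A1 (gene ID 395530, 307.3 against 86.4). MGP (gene ID 395912, 343.9 against 23.1 CPM, 14.9-fold higher, 13.9 to 16) and SPP1 (gene ID 395210, 108.3 against 7.24 CPM) stood beside them. Leukocyte markers were higher in 10 of 11 (median 1.13) with CSF1R (gene ID 396406, 30.2 against 1.69 CPM). All 5 glia markers were higher (median 0.76) with PMP2 (gene ID 420198, 93.4 against 31.7 CPM) and FABP7 (gene ID 396246, 169.2 against 62.4), where glia-like cells were 14.3 against 3.55%. Cholesterol synthesis genes were lower in 13 of 14 (median -0.64, percentile 0.17), as in DHCR7 (gene ID 422982, 33.2 against 72.2 CPM) and MSMO1 (gene ID 422423, 236.6 against 463.2). Interferon response genes were split, 7 higher and 8 lower (median -0.08, -0.91 without capture code SC472 to 0.15 without code SC457 leaving out each capture code). IFI6 (2.18 against 26.1 CPM) was lower. The interferon list of the day 6 control itself stood above day 0 (median 1.40, -0.0034 from the authors' normalized values). The cell cycle list was at 0.29 (-0.27 without capture code SC474 to 1.30 without code SC464 leaving out each code) and the Notch pathway list at 0.07, in which HES5 (4.97 against 26.5 CPM) was lower. SOX2 (1.96 against 4.7 CPM) and TECTB (603 against 1214) were lower and TECTA (19.5 against 19.9 CPM) was level in CPM. SOX2 was read in only 3 treated and 6 control cells. TECTA was read in 5 treated against 17 control cells, 2.75 against 10.06% of cells, so its CPM rests on few cells. Without 1 code the leukocyte median runs from 0.61 without capture code SC470 to 1.85 without code SC458, and the Notch pathway median from -0.08 without capture code SC460 to 0.22 without code SC461.

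In supporting cell-like cells at day 6, which genes separate the treated from the control explants? Cholesterol synthesis genes were lower and YAP and matrix genes higher in 54 treated cells against 58 control cells, which hold 9621338 and 12088011 reads. Cell cycle and Notch pathway genes were lower too, but less firmly. Cluster 10, the one of the weakest markers, is counted in the class, and values that reverse without it are given.

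12 of 13 cholesterol synthesis genes were lower (median -1.13, percentile 0.020, -0.56 from the authors' normalized values): STARD4 (gene ID 769322, 27.5 against 221.6 CPM) and INSIG1 (14.6 against 66.8). The related enzyme gene NSDHL (gene ID 422302, 0.52 against 99.2 CPM) was among the lowest of all. Without cells that have a read of MYO7A, OTOF or CALB2 the NSDHL ratio is 0.90 in place of -6.04. Of 11 cell cycle genes 8 were lower (median -2.87, or -2.99 with zero genes at their bound, -3.17 without capture code SC461 to -0.83 without code SC458 leaving out each code), MCM6 (0 against 44.8 CPM) and RRM2 (gene ID 421936, 0.104 against 21.1) among them. With no minimum CPM the cell cycle median is -0.11. MCM2 (30.8 against 2.4 CPM) was higher. Notch pathway genes were lower in 10 of 13 (median -0.55, percentile 4.585), with HES4 (10.8 against 81.5 CPM) and HES5 (20.1 against 56.01). Interferon response genes were split at 7 higher and 8 lower, IFI6 (0 against 40.8 CPM) and IFIH1 (2.08 against 42.9) being lower. Hair cell genes read in these cells were lower in 17 of 24 (median -0.63), as in CHRNA9 (0 against 28.5 CPM) and TMC1 (gene ID 427255, 18.5 against 92.7) and MYO7A (14.03 against 42.4 CPM, 3.02-fold lower, 2.5 to 3.68). Without cluster 10 the hair cell list stands at 0.27 and MYO7A at 0.50. HES6 (0 against 108.1 CPM) was not read in the treated cells. CTBP2 (gene ID 423958, 86.5 against 0.91 CPM, 95.03-fold higher, 52.8 to 191.1) was higher, against a ribbon synapse list at -1.39 (0.24 without cluster 10). The ribbon protein Ribeye is only 1 of its products, and which product these reads come from was not examined. YAP and matrix genes were higher in 9 of 12 (median 0.80), with COL4A1 (42.9 against 0.496 CPM) and FN1 (48.6 against 1.24) higher and SPARC (gene ID 386571, 0.52 against 36.1 CPM) lower (0.57 without cells that have a read of MYO7A, OTOF or CALB2). So were tectorial membrane and inner ear matrix genes in 8 of 11 (median 0.43, -0.03 from the authors' normalized values). NEXN (gene ID 424552, 429.98 against 5.63 CPM, 76.4-fold higher, 60.2 to 98.6), an actin filament gene, stood far higher, and PSCA (gene ID 420302, 184.8 against 0.0827 CPM) has 1 control read (ratio 2234, 400.4 to 88281). CHD1L (gene ID 418338, 0 against 103.6 CPM, at least 332.2-fold lower) was among the lowest. ATOH1 (242.1 against 235.3 CPM), SOX2 (8.21 against 6.54) and TECTA (79.2 against 56.2) differed less and TECTB (2508 against 3526 CPM) was lower. HES6 and TECTA were read in 3 cells of the higher group, CHRNA9, IFI6, RRM2 and SOX2 in 2 and MCM2 in 1. Leaving out 1 code gives at most -1.70 for the hair cell list (code SC474) and -2.41 for the ribbon synapse list (code SC474).

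How does the tissue after 4 days without the drug compare with the tissue at the end of exposure? From day 2 to day 6 in the streptomycin arm hair cell, bundle and synapse genes were higher. Genes of the cell cycle, the interferon response and the immediate early response were lower, and matrix genes were higher.

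24 of 25 hair cell genes were higher at day 6 (median 1.22, percentile 100, 0.70 from the authors' normalized values), among them CDH23 (gene ID 423718, 25.5 against 2.55 CPM) of the tip link, the transcription factor GFI1 (gene ID 429088, 73.6 against 13.1 CPM), RBM24 (gene ID 420846, 348.3 against 74.8 CPM) and the mechanotransduction channel gene TMC2 (gene ID 428456, 159.97 against 36.5 CPM). Bundle genes were higher in 18 of 21 (median 1.08), with GRXCR2 (21.5 against 1.18 CPM) and PCDH15 (gene ID 423644, 112.8 against 30.8). Ribbon synapse genes were higher in 9 of 11 (median 1.06), with PCLO (gene ID 395319, 77.5 against 13.8 CPM), SLC17A8 (95.9 against 24.9) and OTOF (gene ID 422007, 295.8 against 106.2). MYO7A (174.7 against 96.1 CPM, 1.82-fold higher, 1.72 to 1.92) was higher and ATOH1 (427.1 against 396.5 CPM, 1.08-fold higher, 1.05 to 1.11) was close. In the nascent hair cell list 8 of 12 were higher (median 0.84, -0.12 from the authors' normalized values), but HES6 (2.79 against 26.1 CPM) was lower. Mesenchyme genes were higher in 10 of 13 (median 1.22), COL6A3 (gene ID 396548, 404.1 against 85.1 CPM) and POSTN (gene ID 395429, 681 against 132.6 CPM) among them, POSTN being -0.25 in place of 2.35 with the fixed thresholds. YAP and matrix genes were higher in 10 of 15 (median 1.09, -0.08 from the normalized values), with FN1 (1043 against 148.5 CPM). NEXN (211.7 against 11.7 CPM, 18.1-fold higher, 15.6 to 21.1), CRABP1 (gene ID 374211, 125.9 against 7.6 CPM, 16.6-fold higher, 13.8 to 20.1) and the Schwann cell cadherin gene CDH19 (gene ID 421029, 115.3 against 7.2 CPM, 16-fold higher, 13.2 to 19.5) stood high. Cell cycle genes were lower in 13 of 16 (median -1.13, -1.46 without capture code SC468 to -0.23 without code SC512 leaving out each code): UBE2C (gene ID 100859413, 10.8 against 62.5 CPM), BIRC5 (13.4 against 60.5) and CENPF (26.3 against 114.2). 10 of 15 interferon response genes were lower (median -0.63), IFI6 (2.18 against 370.8 CPM, 170-fold lower, 137.9 to 212.03) and IFIT5 (gene ID 423790, 6.1 against 53.2 CPM) among them. All 10 immediate early genes were lower (median -0.33), as in EGR1 (gene ID 373931, 18.2 against 75.4 CPM) and FOS (gene ID 396512, 9.9 against 26.2). AVDL (gene ID 431660, 15.98 against 324.3 CPM, 20.3-fold lower, 18.7 to 22.1), HES5 (4.97 against 83.3 CPM, 16.7-fold lower, 14.4 to 19.5) and DLL1 (28.6 against 67.5 CPM) and LFNG (55.04 against 114.4) were lower, while the Notch pathway list as a whole stood at 0.44. TECTB (603 against 1411 CPM), TECTA (19.5 against 42.96) and SOX2 (1.96 against 8.71) were lower, SOX2 being read in only 3 day 6 and 5 day 2 cells. Without code SC508 the ribbon synapse median is 1.76.

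In the ATOH1-led cluster alone, a comparison chosen after the data were seen, 35 day 6 streptomycin cells were set against 15 at day 2. Which day 2 cells it holds depends on the setting. With fixed thresholds the ATOH1-led cluster holds 2 day 2 and 37 day 6 streptomycin cells. An unnamed cluster with PENK, ATOH1 and EDNRB2 among its leading genes then holds 34 and 4. Apart from leaving out capture codes no alternative was run on this comparison, so it may set cells of different clusters against each other. The median of all genes in this comparison lies at 0.21. Its hair cell genes were higher at day 6 in 22 of 24 (median 1.96), bundle genes in 22 of 23 (median 2.11) and cholesterol synthesis genes in 13 of 13 (median 1.63). MYO7A (637 against 0 CPM, at least 427.8-fold higher) was read in 26 of 35 cells against 0 of 15 (at most 20%). TMC2 (651 against 0 CPM, at least 437.4-fold higher) was likewise unread at day 2, and OCM (2994 against 0.496 CPM) had 1 read there. HES6 (13.1 against 172.7 CPM) and HES5 (0.115 against 130.02) were lower, and ATOH1 (1724 against 2231 CPM) differed less. Among genes picked by hand after the data were seen, the Notch ligand gene DLL1 (116.5 against 470 CPM), the enkephalin precursor gene PENK (212.8 against 4605) and the endothelin receptor gene EDNRB2 (425.9 against 1950) were lower too. The day 6 control cells of the cluster, 22 in number, lie near the day 6 streptomycin cells in PENK (399.4 CPM), MYO7A (460), OCM (3958) and TMC2 (498.1). HES6 was read in 66.7% of the day 2 cells, 11.4% of the day 6 streptomycin cells and 13.6% of the day 6 control cells. In CPM, however, HES6 in these control cells is at 121.35, from 3 cells, against 13.1 with streptomycin at day 6 and 172.7 at day 2. Without 1 capture code the bundle list reaches 2.88 and the cholesterol list 2.62 (code SC507 for both).

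**Figure D3:**
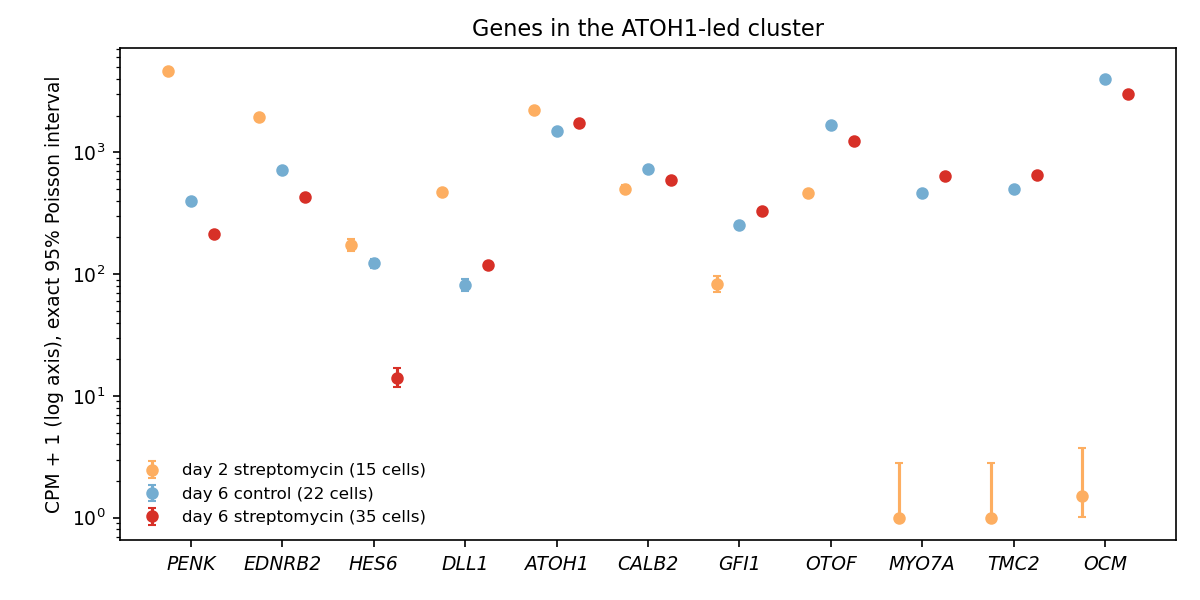
Expression of 11 genes in the ATOH1-led cluster as CPM + 1 on a log axis, summed over 15 day 2 streptomycin, 22 day 6 control and 35 day 6 streptomycin cells; points are sums and bars exact 95% Poisson intervals. PENK lies at 4605 CPM at day 2 and at 399.4 and 212.8 CPM at day 6, and OCM at 0.496, 3958 and 2994 CPM.

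What does 24 h of preincubation alone do before any drug is added? Supporting cell and tectorial membrane genes were lower at day 0 than in intact tissue, and glycolysis and hypoxia genes were higher. Hair cell genes lay near their starting level. Interferon response, immediate early and Notch pathway genes were lower.

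15 of 16 supporting cell genes were lower at day 0 (median -1.40, percentile 0): the tectorin gene TECTB (1236 against 8290 CPM, 6.71-fold lower, 6.62 to 6.8), the gap junction gene GJB6 (gene ID 395771, 239.2 against 1316 CPM), the growth factor receptor gene FGFR3 (gene ID 396515, 73.3 against 381.1 CPM) and TECTA (24.5 against 117.5 CPM). The tectorial membrane and inner ear matrix list was lower in 7 of 10 (median -1.38), OTOA (gene ID 416624, 68.8 against 271.4 CPM) included. Beside this stand supporting cell-like shares of 14.8 against 31.8%. SOX2 (1.82 against 2.25 CPM) was low in both. Glycolysis and hypoxia genes were higher in 14 of 15 (median 1.41, percentile 100), with ALDOC (gene ID 395492, 239.1 against 25.6 CPM), LDHA (gene ID 396221, 827 against 127.5) and PGK1 (gene ID 395833, 486.3 against 126.96) and the oxygen sensor gene EGLN3 (gene ID 423316, 990.4 against 286.7 CPM). Hair cell genes divided into 12 higher and 14 lower (median -0.08), with OTOF (1175 against 2519.8 CPM) lower, LOXHD1 (gene ID 427648, 2419.6 against 1252 CPM) higher and MYO7A (566 against 500.6 CPM) near level. 13 of 14 interferon response genes were lower (median -0.85, percentile 0.010), IFI6 (6.6 against 92.4 CPM), TRIM25 (gene ID 417401, 5.07 against 31.1) and IRF1 (gene ID 396384, 5.76 against 29.4) among them. Immediate early genes were lower in 8 of 10 (median -0.97), as in FOS (13.6 against 40.7 CPM), BTG2 (gene ID 419932, 70.5 against 197.5) and NR4A3 (gene ID 420996, 241.8 against 616), with FOSL2 (gene ID 421416, 112.1 against 39.4 CPM) higher. Notch pathway genes were lower in 10 of 13 (median -0.46), HEY2 (33.01 against 134.2 CPM) included, but the ligand gene DLL1 (32.2 against 5.8 CPM) was higher. FGF pathway genes were lower in 9 of 11. Integrated stress response genes were higher in 7 of 10 (median 0.71) and mesenchyme genes in 7 of 8 (median 1.99, 1.17 without capture code SC484 to 2.13 without code SC480). ATOH1 (4.93 against 18.95 CPM, 3.85-fold lower, 3.08 to 4.84) was lower. The highest single ratio was that of the prostaglandin D synthase gene HPGDS (gene ID 395863, 502.9 against 0.138 CPM), with 3 reads in intact tissue (ratio 3644, 1246 to 17673). SNCB (gene ID 395391, 52.5 against 0.966 CPM), EXFABP (gene ID 396393, 51.6 against 1.24) and UPP1 (gene ID 420942, 61.3 against 1.89) were also high, and PCP4 (gene ID 771220, 6.75 against 86.02 CPM) and the prolactin receptor gene PRLR (gene ID 395660, 48.7 against 494.4 CPM, 10.2-fold lower, 9.51 to 10.8) were among the lowest.

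How do control explants at day 2 and day 6 differ from day 0, without any drug? Mesenchyme and matrix genes were far higher at both days, and ATOH1 was higher, while hair cell genes were moderately lower. By day 6 matrix genes of the inner ear, Notch pathway, interferon response and inflammatory genes were higher too.

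At day 2 all 12 mesenchyme genes were higher (median 3.72), LUM (58.9 against 0 CPM, at least 398.4-fold higher), COL1A2 (491.2 against 7.29 CPM) and POSTN (230.7 against 5.27) among them, where mesenchyme-like cells were 17.0 against 2.12%. PMP2 (145.6 against 0 CPM, at least 985-fold higher), a myelin gene, was unread at day 0. LGALS1 (gene ID 396491, 761 against 5.72 CPM, 133.1-fold higher, 110.9 to 161.2) and APOA1 (gene ID 396536, 1044 against 9.21 CPM, 113.3-fold higher, 98.1 to 131.6) were also high. All 15 YAP and matrix genes were higher (median 2.11), with ACTA2 (81.6 against 0.641 CPM), SPARC (28.5 against 1.63) and CYR61 (43.5 against 6.65). So were all 10 immediate early genes (median 1.11). 23 of 27 hair cell genes were lower (median -0.58, percentile 0), GFI1 (57.4 against 134.1 CPM) and TMC2 (330.8 against 733) included, and MYO7A (464.3 against 566 CPM) with them. ATOH1 (65.9 against 4.93 CPM, 13.4-fold higher, 10.9 to 16.6) was higher. SOX2 (0.803 against 1.82 CPM) and TECTB (726 against 1236) were lower and TECTA (25.5 against 24.5 CPM) was level. SOX2 was read in only 1 day 2 control and 4 day 0 cells. Supporting cell genes were higher in 11 of 16 (median 0.42, -0.04 from the authors' normalized values), as in LFNG (30.7 against 8.97 CPM) and GJB2 (gene ID 428083, 133.6 against 43.2). The doublet call takes 63 of the 94 control cells. Without them the hair cell list stands at 0.02, the supporting cell list at -0.91, the immediate early list at -0.68, ATOH1 at -0.54, LFNG at -3.33, ACTA2 at -0.51 and MYO7A at 0.65, so the signs of these 7 values at day 2 hang on that filter. The mesenchyme median runs from 3.26 without capture code SC505 to 4.82 without code SC484. The 3 erythrocyte genes were higher (median 4.80), but stand at -0.07 without code SC503.

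At day 6 all 11 measured mesenchyme genes were higher again (median 4.11), with COL1A2 (552 against 7.29 CPM) and LUM (72.97 against 0 CPM, at least 493.7-fold higher). So were all 14 YAP and matrix genes (median 2.52), CTGF (93.7 against 4.88 CPM) among them. EPYC (gene ID 417890, 253.7 against 0 CPM, at least 1716-fold higher), which encodes the proteoglycan epiphycan, had no read at day 0. EDNRB2 (gene ID 373909, 131.1 against 0.542 CPM, 241.9-fold higher, 135.1 to 484.8) and GIF (282.5 against 1.72 CPM, 163.8-fold higher, 117.7 to 235.3) came next. Inner ear matrix genes were higher in 8 of 11 (median 2.25), COCH (1948 against 97.9 CPM), COL9A2 (gene ID 396524, 142.99 against 12.1) and OC90 (299.8 against 38.4) included. Supporting cell genes were higher in 12 of 16 (median 0.98), with PROX1 (gene ID 395802, 63.4 against 9.12 CPM), LFNG (50.8 against 8.97) and OTOG (gene ID 423075, 223.4 against 44.2). Notch pathway genes were higher in 12 of 13 (median 1.03), as in HES4 (52.6 against 10.1 CPM) and NOTCH1 (gene ID 395655, 104.5 against 36.8). Interferon response genes were higher in 11 of 15 (median 1.40, -0.0034 from the authors' normalized values), with IRF1 (56.6 against 5.76 CPM). JAK-STAT and inflammatory genes were higher in 13 of 14, with SOCS3 (gene ID 395299, 21.3 against 0.887 CPM). 24 of 27 hair cell genes were lower (median -0.70, percentile 0), CIB2 (gene ID 415363, 358.4 against 910.1 CPM) and CACNA1D (205.5 against 480.3) among them, against a higher CALB2 (gene ID 396255, 141.9 against 4.83 CPM, 29.4-fold higher, 24.1 to 36.3). ATOH1 (249.3 against 4.93 CPM, 50.6-fold higher, 41.6 to 62.3) was higher beside a 13.02% share of the ATOH1-led cluster, absent at day 0, and HES6 (50.5 against 0 CPM) with it. MYO7A (412.9 against 566 CPM) and TECTA (19.9 against 24.5) were lower, SOX2 (4.7 against 1.82 CPM) was higher and TECTB (1214 against 1236 CPM) was level. SOX2 was read in only 6 day 6 control and 4 day 0 cells. Among the lowest genes were C14orf180 (gene ID 423490, 0.0282 against 156.2 CPM) with 1 read at day 6 (ratio 5549.5, 995 to 219260) and the somatostatin-related SS2 (gene ID 395106, 20.4 against 153.7 CPM, 7.52-fold lower, 6.94 to 8.16). Leaving out each code takes the mesenchyme median from 3.58 without capture code SC463 to 5.45 without code SC484.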

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

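All 9 tests in this part were chosen only after the result was seen. The lower hair cell-like share with streptomycin is the first pattern, and the technical explanations weighed are the cell filter, depth per cell and a single capture code. Depth is argued against by the hair cell list in CPM, which does not move with reads per cell: its median of 27 genes is -2.37 at day 2 (-2.68 to -2.22 leaving out each code) and -0.81 at day 6 (-0.95 to -0.75). A single capture code is argued against too, since the highest share with streptomycin leaving out 1 code is 18.6% against a lowest control share of 40.5% at day 2, and 21.95 against 37.1% at day 6. Over all sites with 200 genes or more the shares were 9.16% (6.46 to 12.5) with streptomycin against 13.6% (10.3 to 17.4) at day 2 and 10% (7.24 to 13.4) against 17.8% (14.1 to 21.9) at day 6. The day 6 control share counts the 40 sites of capture code SC462 described below among all sites. An unnamed cluster of the sites with 200 genes or more has OCM, LOXHD1 and OTOF among its leading genes. The supporting cell gene TECTB is among them too, so its type is open. Counting this cluster as hair cell-like in both arms gives 11.5 against 26.2% and 10 against 27.75%. Other unnamed sites, many of them led by mitochondrial genes, have no known type. With all unnamed sites of the streptomycin arm counted as hair cells, and none of the control's, the share of that arm would be 56.5% at day 2 and 27.5% at day 6. This bound is 1-sided. The control holds unnamed sites too, and with those of both arms counted its share would stay the higher at both days. The type of these sites is open and may differ between the arms, so the filter cannot be told apart from the drug at either day. Loss of hair cells to streptomycin may explain the pattern and stays open, because each arm is 1 sample with nothing to separate drug from culture.

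Among the sites left out of the main comparisons, capture code SC462 of the day 6 control stood apart: none of its 40 sites was kept, and the median is 8827 detected genes per site, with 3240 to 9738 over its sites, although its median depth is 168676 reads. The threshold and loose filters do hold these sites. With the threshold filter the day 6 control share of hair cell-like cells is 31.2% with this code and 37.1% without it. The code accounts for 37 of the 92 sites with more genes than any kept cell. After thinning to 5000 reads 85% of its sites (70.2 to 94.3) hold reads of OTOF, TECTB and COL1A2 together, markers of hair cells, supporting cells and mesenchyme, against no kept cell of the group (at most 1.78%). Many reads with 1 cell per site is argued against by 2324 median genes after thinning, against 1073 in kept cells of the group. RNA of many cells in each site fits these values and is a candidate explanation, for example a bulk or pooled input, which the labels do not name. Its sum correlates with that of the day 6 control at 0.575 and with the next group at 0.559, so material of another group cannot be told apart from it by this value. Its levels are 453 CPM for OTOF, 191.1 for MYO7A, 1007 for TECTB, 1232 for COL1A2 and 17.2 for ATOH1, and no biological explanation was tested.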

How the results depend on the processing

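Chosen only after the data were seen were 3 alternatives: leaving out the 5% of cells with the highest doublet scores, the threshold filter without capture code SC462, and the supporting cell-like comparisons without cluster 10. With 1 sample per group nothing shows how far cultures differ, and intervals cover counting error only. No paired analysis was possible because no label pairs the groups. Of 2344 alternative values of list medians, 1870 lay within the range from leaving out each capture code, 452 moved and 22 reversed a clear direction, meaning a sign that holds without each code in a median among the outer 5% of random lists. In all 2160 kept the sign of the main value, and the rest beyond these reversals had a main value short of that bar or lay at 0. Of 2906 values of named genes, 1955 lay within, 934 moved and 17 reversed a direction that holds without each code and beyond the counting interval, and 2861 kept the sign. Of the alternative values of 84 shares, 74 lay within the exact interval and 58 moved. The hair cell-like share with streptomycin was below the control share at both days under each alternative tried. The values that moved in a main result or reversed a clear direction follow, with the main value in brackets, list medians and genes as log2 ratios. The cause was not tested except where the construction shows it.

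The threshold cell filter gives hair cell-like shares of 60.9% intact (67.8), 7.25% day 2 streptomycin (16.96), 31.2% day 6 control (40.8), and for day 2, hair cell -2.21 (-2.37), and for day 2 in supporting cell-like cells, cell cycle 4.52 (2.95), ATOH1 -1.17 (1.23), MCM2 -0.84 (4.65), TECTB -0.29 (0.29). It gives, for recovery, hair cell 0.97 (1.22), POSTN -0.25 (2.35). The loose filter gives hair cell-like shares of 45.9% intact (67.8), 51.4% day 0 (76.7), 13.6% day 2 control (43.6), 9.16% day 2 streptomycin (16.96), 17.8% day 6 control (40.8), 10% day 6 streptomycin (20.3). Counting cells with 4 or more markers after thinning gives hair cell-like shares of 95.02% intact (67.8), 91.1% day 0 (76.7), 55.3% day 2 control (43.6), 37.5% day 2 streptomycin (16.96), 59.2% day 6 control (40.8), 29.7% day 6 streptomycin (20.3). Double the clustering resolution gives hair cell-like shares of 3.57% day 2 streptomycin (16.96). Without the called doublets, 63 of them in the day 2 control, where the call failed, there are hair cell-like shares of 74.2% day 2 control (43.6), and for day 2, hair cell -3.40 (-2.37), interferon response 3.19 (2.04), and for day 2 in supporting cell-like cells, interferon response 4.83 (2.11), cell cycle 3.76 (2.95), glycolysis and hypoxia 1.24 (-0.44), cholesterol synthesis 0.11 (-0.62), CANT1 0.35 (-7.07), JAK2 1.90 (-3.75). There are also, for culture to day 2, hair cell 0.020 (-0.58), supporting cell -0.91 (0.42), bundle 0.046 (-0.57), immediate early -0.68 (1.11), cholesterol synthesis -0.11 (0.39), ACTA2 -0.51 (5.65), ATOH1 -0.54 (3.50), DAB2 -0.071 (6.36), LFNG -3.33 (1.67), MYO7A 0.65 (-0.28). From the authors' normalized values come, for day 2, hair cell -2.09 (-2.37), and for day 6, hair cell -0.60 (-0.81), mesenchyme 1.23 (1.64), and for day 2 in supporting cell-like cells, cell cycle 1.43 (2.95), glycolysis and hypoxia 0.087 (-0.44). There are also, for day 6 in supporting cell-like cells, inner ear matrix -0.028 (0.43), cholesterol synthesis -0.56 (-1.13), and for recovery, hair cell 0.70 (1.22), nascent hair cell -0.12 (0.84), YAP and matrix -0.080 (1.09), and for preincubation, supporting cell -1.20 (-1.40), glycolysis and hypoxia 0.78 (1.41). There are also, for culture to day 2, hair cell -0.77 (-0.58), supporting cell -0.038 (0.42), mesenchyme 2.46 (3.72), and for culture to day 6, hair cell -1.22 (-0.70), mesenchyme 2.57 (4.11), BMP and TGF-beta targets -0.0036 (0.77), interferon response -0.0034 (1.40), integrated stress response -0.17 (0.93), cholesterol synthesis -0.32 (0.64), oxidative stress defence -0.34 (0.75). TMM scaling gives, for preincubation, glycolysis and hypoxia 1.32 (1.41). With equal weight per cell there is, for culture to day 2, hair cell -0.80 (-0.58). A pseudocount of 5 CPM, which shrinks ratios by construction, gives, for day 2, hair cell -2.18 (-2.37), and for culture to day 2, mesenchyme 3.07 (3.72), and for culture to day 6, mesenchyme 3.53 (4.11). A pseudocount of 0.1 CPM, which stretches them, gives, for day 2, cell cycle 2.25 (1.94), and for day 2 in supporting cell-like cells, cell cycle 5.04 (2.95), and for day 6 in supporting cell-like cells, cell cycle -5.27 (-2.87). With no minimum CPM, which adds near-empty genes, come, for day 6 in supporting cell-like cells, cell cycle -0.11 (-2.87), and for preincubation, supporting cell -1.03 (-1.40), and for culture to day 2, Wnt pathway -0.12 (1.17). Without cells that have a read of MYO7A, OTOF or CALB2 there are, for day 2 in supporting cell-like cells, cell cycle 3.35 (2.95), TECTB -0.068 (0.29), and for day 6 in supporting cell-like cells, NSDHL 0.90 (-6.04), SPARC 0.57 (-4.61). Without the 5% of cells with the highest doublet scores come, for day 2, hair cell -2.72 (-2.37), interferon response 2.18 (2.04), and for day 2 in supporting cell-like cells, glycolysis and hypoxia 0.11 (-0.44), and for recovery, hair cell 1.70 (1.22). There are also, for preincubation, glycolysis and hypoxia 1.36 (1.41), and for culture to day 2, hair cell -0.50 (-0.58). The threshold filter without capture code SC462 gives hair cell-like shares of 60.3% intact (67.8), 7.25% day 2 streptomycin (16.96). The day 6 control share, 31.2% with that code, is then 37.1% (40.8) and lies within the interval of the main value. Without cluster 10 there are, for day 2 in supporting cell-like cells, interferon response 3.56 (2.11), cell cycle 0 (2.95), TOP2A -0.43 (4.61), and for day 6 in supporting cell-like cells, hair cell 0.27 (-0.63), bundle 0.022 (-0.81), ribbon synapse 0.24 (-1.39), CRISP2 -2.67 (5.61), MYO7A 0.50 (-1.53).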

Other observations

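The comparisons in this part were chosen after the data were seen: preincubation within each class and streptomycin at day 6 within the ATOH1-led cluster. Did the glycolytic response to 24 h of preincubation sit in 1 cell type? It was found in both main classes, with glycolysis and hypoxia genes higher in 12 of 14 in hair cell-like cells (median 1.28) and in 13 of 14 in supporting cell-like cells (median 1.81, in 35 against 83 cells). In hair cell-like cells ALDOC (200.3 against 14.2 CPM) and SLC16A3 (gene ID 395383, 279.1 against 43.8) and the uridine phosphorylase gene UPP1 (69.5 against 0.529 CPM, 131.5-fold higher, 66.5 to 305.3) were higher, and in supporting cell-like cells EGLN3 (1193 against 79.02 CPM) and LDHA (1137 against 85.6). The proton pump subunit gene ATP6V1C2 (gene ID 421939, 110.3 against 1089.6 CPM, 9.88-fold lower, 9.4 to 10.4) was lower in hair cell-like cells, read in 40.9% at day 0 against 95.5% in intact tissue, as were PCP4 (8.62 against 119.01 CPM) and S100B (gene ID 424038, 11.01 against 90.8). Hair cell genes there were lower in 16 of 25 (median -0.22), with OTOF (1492 against 3572 CPM) lower and MYO7A (714 against 712 CPM) level, and immediate early genes in 9 of 10 (median -0.79).

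The 2 classes parted in cholesterol synthesis, where all 14 genes were higher at day 0 in supporting cell-like cells (median 1.28), LSS (gene ID 424037, 61.9 against 10.4 CPM) and INSIG1 (280.1 against 86.2) among them, and 8 of 13 were lower in hair cell-like cells (median -0.19). The difference between the classes was not tested. Interferon response genes were lower in both, more in supporting cell-like cells (14 of 16, median -2.21, percentile 0) than in hair cell-like cells (8 of 11, median -0.76), as in PARP9 (gene ID 424269, 0 against 39.3 CPM) and TRIM25 (0.741 against 58.8). HPGDS (2260.5 against 0 CPM, at least 4911-fold higher), which encodes a prostaglandin D synthase, was read in 65.7% of day 0 supporting cell-like cells and had no read in the intact ones. TECTB (8070.1 against 26635 CPM, 3.3-fold lower, 3.25 to 3.35) was lower within the class as well. Nearly all intact supporting cell-like cells lie in cluster 4 and most of those at day 0 in cluster 3, so cell state and library are not separable here.

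In the ATOH1-led cluster at day 6, 35 streptomycin cells against 22 control cells, hair cell genes divided into 15 higher and 11 lower (median 0.32) and ribbon synapse genes into 5 and 7 (median -0.44). CDH23 (108.1 against 11.7 CPM, 9.23-fold higher, 6.89 to 12.7) and NOTCH1 (75.5 against 1.25 CPM) were higher with streptomycin, and CHRNA9 (0 against 101.4 CPM, at least 293.6-fold lower), read in 3 of the control cells, and USH1C (gene ID 423073, 54.6 against 420.4 CPM, 7.7-fold lower, 6.95 to 8.54) lower. MYO7A (637 against 459.98 CPM) was higher. Control explants hold such cells without any drug.

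ATOH1-led cells in the day 6 control were weighed as a pattern, with 3 tests chosen after the result was seen. Carry-over of reads that reaches all cells alike is argued against: mesenchyme-like, glia-like and leukocyte-like cells of that group, 29 in all, hold ATOH1 at 1.77 CPM (0.847 to 3.25), against 1490 CPM (1452 to 1528) in the 22 ATOH1-led cells. Supporting cell-like cells of the group hold far more ATOH1 than those 29, as given above, and were left out of this test. The cluster was also picked by its ATOH1, so carry-over between it and supporting cell-like cells stays open. No capture code holds most of the ATOH1-led cells, since the largest part from 1 code is 27.3%, and they come from 9 codes. For sites with 2 cells, median genes per cell after thinning were set against those of the other kept cells of the group, a ratio of 1.06 (1410 against 1331). How far 2 cells in 1 site would raise this ratio was not measured, so this test cannot decide on such sites. That some hair cell-like cells form in culture without streptomycin stays a hypothesis from 1 control sample.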
